A study of Homo sapiens with 9 samples.

How the data were processed

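Gene expression was measured by RNA sequencing of primary human coronary artery endothelial cells grown on the upper face of transwell membranes. The 9 libraries form 3 groups of 3, per the labels. In the monolayer group the endothelial cells grew alone. In the no-contact group coronary artery smooth muscle cells grew on the floor of the well, so that only medium was shared. In the contact group the smooth muscle cells grew on the lower face of the same membrane. Per the submitters' design notes, every group had endothelial growth medium above the membrane and smooth muscle medium below it. The labels do not say whether the replicates of a group are separate cultures or donors, or what the replicate numbers mark.

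Per the submitters' processing notes, paired-end reads were mapped to hg38 with STAR 2.7.9a and the authors counted reads per gene with featureCounts, giving the deposited table of raw counts. The annotation release and the strand setting of the counting are not stated. The deposited table of normalized signal holds the counts divided by a size factor per library, which was checked against the count table. It lists the 17136 genes whose total over the libraries is at least 51 counts. The authors tested each pair of groups with DESeq2 1.34.0, per the submitters' processing notes, and deposited for each gene a log2 fold change with its standard error and a p-value, raw and adjusted. The raw counts were the starting point here. The authors' comparison tables were used only to set their calls beside those made here.

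Of the 61860 gene IDs in the count table, 61757 matched GENCODE release 44 on hg38, which supplied symbols and coordinates, and 103 did not match. For 12 of the unmatched IDs, SOD2 among them, the deposited tables gave a symbol, and these have no coordinates here. XIST and Y-linked genes were left out of every table, 528 genes in all.

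The main test was edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its minimum count of 10 and minimum total of 15, libraries were scaled by TMM, and a model with a mean per group was fitted to all 9 libraries at once. Each pair of groups was compared with the quasi-likelihood F test, and p-values were adjusted by the method of Benjamini and Hochberg over the 16433 genes tested. A gene was called at an adjusted p below 0.05. Fold changes and their standard errors (SE) are on the log2 scale where stated. Levels are CPM, edgeR's counts relative to the TMM-scaled library total, with SD over the 3 libraries of a group. A further F test asked which genes differ among the 3 groups in any way.

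Before the data were examined, 29 gene lists were written for endothelial identity and subtypes, mural and other cell types, signalling, matrix, vascular function, proliferation and metabolism. The 28 with at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The epithelial list, with 2 tested genes, was not tested. Camera with a correlation estimated per list, and the rotation test fry, were alternatives. Each list score is the mean log2 CPM of the list's tested genes in a library, minus the mean over the monolayer libraries, with a prior count of 2.

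The genes named were also set by a rule written before the data were examined. Per comparison it took, among called genes with a symbol, at least 10 CPM in the higher group and no overlap between the groups, the 8 largest rises and the 8 largest falls. It added up to 4 genes per list by smallest p, and a fixed set of endothelial, smooth muscle and signalling genes. Any other gene named was chosen after its values were seen, which is said where it occurs.

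The groups share libraries, so the effects of both co-cultures against the monolayer were also set beside 20 simulated data sets in which neither co-culture differed from it. In another 20, both co-cultures had the same effects. The calling of genes was tested on simulated data, with 16074 genes tested by edgeR and 200 changed genes counted for recovery, 50 per fold size. These genes were drawn from the better-expressed ones, so the shares recovered do not cover genes with low counts. In contact against monolayer the edgeR step called 62% of the genes changed 1.5-fold and 100% of those changed 2-fold, with 14 false calls. In contact against no-contact it called 62% of the genes changed 1.5-fold and 96% of those changed 2-fold, with 10 false calls. In no-contact against monolayer, left unchanged, it made 1 false call. DESeq2 1.42.0 called 182 of the 200 in contact against monolayer, with 22 false calls. The simulated libraries hold no shift common to many genes of a library, so false calls in the real data may be more frequent.

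The alternatives tried were other scaling factors (DESeq2 size factors and upper-quartile factors), DESeq2 as the test, no filter and a stricter filter on low counts, fits of only the groups compared, a minimum fold change, the replicate number as a block, each library left out in turn, and, chosen after the data were seen, all libraries thinned to the smallest total. Total counts ranged from 19193002 to 32874573 per library. Counting intervals and the floor of 3 counts for a gene with none cover counting error only, since reads without molecular identifiers are not independent molecules.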

Results

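The data are raw read counts per gene for 3 monolayer, 3 no-contact and 3 contact libraries of human coronary artery endothelial cells, so each group has n = 3. Total counts were 32874573, 27861929 and 32306011 in the monolayer libraries, 24308639, 19193002 and 30897136 in the no-contact libraries and 31122908, 32708356 and 28448545 in the contact libraries. Between 21524 and 22891 genes had a count in a library, and 16433 passed the filter for testing. Every library carried high levels of endothelial transcripts. PECAM1, an adhesion molecule of endothelial junctions, stood at 2023 ± 227 CPM (SD, n = 3) in monolayer, 2229 ± 66.6 in no-contact and 2133 ± 30.5 in contact. CDH5, the endothelial cadherin, stood at 1406 ± 156, 1391 ± 209 and 1433 ± 94.2 CPM. The smooth muscle genes ACTA2 and MYH11 were far lower, at 8.51 ± 2.12 and 0.546 ± 0.316 CPM in monolayer. On the first principal component, which held 27.1% of the variance, the contact libraries lay at 22.5 to 50.6, the no-contact libraries at −15.6 to 5.44 and the monolayer libraries at −35.4 to −15.2. Contact replicate 3, at 50.6, was the farthest out. Because the labels do not say that replicates are separate cultures or donors, the p-values measure only the spread between these samples, which may be technical.

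Contact against monolayer asks what endothelial cells express differently with smooth muscle cells on the other face of the membrane. Several chemokines and the complement genes C3 and C1S were among the largest rises. C3, the central complement protein (ENSG00000125730, hg38 chromosome 19, 6677704 to 6730562), had 2 counts over the 3 monolayer libraries and 6404 over the 3 contact libraries, a ratio of 3228 after correction for depth (95% counting interval 893 to 26664). Its level with contact was 69.8 ± 9.76 CPM (SD, n = 3). C1S, a protease of the classical complement pathway (ENSG00000182326, chromosome 12, 6988259 to 7071032), rose 51.0-fold from 0.236 ± 0.0663 CPM. For C3 and C1S a trace of smooth muscle RNA among the reads was not excluded, and was not tested against monolayer. The neutrophil-attracting chemokines CXCL6 (ENSG00000124875, chromosome 4, 73836640 to 73849064), CXCL1 and CXCL2 rose 38.5-fold, 23.7-fold and 21.3-fold. CXCL1 reached 907 ± 234 CPM. The monocyte chemoattractant CCL2 rose 15.5-fold, and the granulocyte growth factor CSF3 rose 30.1-fold to 82.7 ± 48.1 CPM, with a wide spread between the contact libraries.

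The largest falls with contact were in vessel wall and signalling genes. PLVAP, which forms the diaphragms of endothelial caveolae and fenestrae (ENSG00000130300, chromosome 19, 17351450 to 17377342), was 8.40-fold lower, at 3.23 ± 0.369 CPM (SD, n = 3) against 27.2 ± 4.35 in monolayer. The arterial gap junction genes GJA4 (ENSG00000187513, chromosome 1, 34792999 to 34795747) and GJA5 (ENSG00000265107, chromosome 1, 147756199 to 147773362) fell by 2.14 and 1.81 on the log2 scale. SMAD6, an inhibitor of BMP signalling, fell by 1.61, the integrin subunit ITGB4 by 1.78, PITPNM3 by 1.82 and ZNF704 by 1.41. The endothelial nitric oxide synthase NOS3 (ENSG00000164867, chromosome 7, 150991017 to 151014588) fell by 0.87, to 185 ± 31.2 CPM from 337 ± 36.9. PECAM1 and CDH5 had log2 fold changes of 0.08 and 0.03 and were not called.

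Of the inflammatory activation list, 24 of 32 tested genes rose with contact, 1 fell and 7 were not called, with 26 and 1 when adjusted over the list alone. The median log2 fold change was 2.25 (adjusted p = 7.98e-113, camera), and the call held with an estimated correlation (adjusted p = 0.00157). The gene that fell was SELP, the platelet and endothelial selectin, at −0.81. Of 41 cell cycle genes 14 rose and none fell, 23 when adjusted over the list alone, with a median of 0.40 (adjusted p = 4.22e-08). The mitotic kinase PLK1 rose by 0.59. The cell cycle call was lost with an estimated correlation (adjusted p = 0.730 with an estimated correlation). Monolayer replicate 2 had a cell cycle score of 0.39, inside the 0.37 to 0.46 of the contact libraries, while the other monolayers had −0.16 and −0.23.

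The lists of matrix remodelling enzymes and of basement membrane genes rose on balance. The mural matrix list did not, with 7 of 22 higher and 7 lower, and was not called. Of 26 matrix remodelling enzymes 10 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.38; adjusted p = 0.000396). The lysosomal collagenase CTSK rose by 1.28, the secreted proteases ADAMTS1 and ADAMTS9 by 1.30 and 1.29, and the protease inhibitor SERPINE2 by 0.94. Of 21 basement membrane genes 4 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.12; adjusted p = 0.0322). The collagens COL8A1, COL4A6 and COL4A5 rose by 1.01, 1.15 and 0.60, and TINAGL1 fell by 0.44. Of 23 glycolysis genes 4 rose and none fell (4 and 1 adjusted over the list alone; median 0.12; adjusted p = 0.0385). The glucose transporter SLC2A3 rose by 0.64 and lactate dehydrogenase LDHA by 0.40. These calls were lost with an estimated correlation (adjusted p = 0.648, 0.777 and 0.678 with an estimated correlation). The basement membrane call ended without monolayer replicate 1 (adjusted p = 0.113), contact replicate 1 (0.143) or contact replicate 2 (0.0545), and with the stricter filter. The glycolysis call ended without the same libraries (0.0714, 0.137 and 0.0657) and also with upper-quartile factors, with the stricter filter and after thinning, and held in 6 of 15 alternatives in all.

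Lists of endothelial specialisation fell on balance with contact. Of 30 endothelial identity genes 9 fell and 2 rose (10 and 2 adjusted over the list alone; median −0.13; adjusted p = 0.000400), among them PLVAP, NOS3, the sialomucin EMCN at −0.76 and the transcription factor SOX18 at −0.95. Of 16 targets of the flow-responsive factors KLF2 and KLF4, 7 fell and 2 rose (7 and 2 adjusted over the list alone; median −0.40; adjusted p = 0.000400). KLF2 itself fell by 0.71 and the quinone reductase NQO1 by 0.55, and ADAMTS1 was 1 of those that rose. Of 18 Notch pathway genes 6 fell and 2 rose (7 and 2 adjusted over the list alone; median −0.29; adjusted p = 0.00573). The ligand JAG2 fell by 0.91, the glycosyltransferase LFNG by 1.04 and the target HES1 by 0.70, while the receptor NOTCH2 rose by 0.92. Of 18 arterial genes 6 fell and none rose (6 and 1 adjusted over the list alone; median −0.04; adjusted p = 0.00573), GJA4, GJA5, the calcification inhibitor MGP at −0.83 and the transcription factor SOX17 at −0.46 among them. The lists overlap, so their falls are not separate evidence. PLVAP and NOS3 belong to both the identity and the KLF2 and KLF4 lists, SOX17 to the identity and arterial lists, and DLL4 to the Notch and arterial lists. These 4 calls were lost with an estimated correlation (adjusted p = 0.656, 0.399, 0.648 and 0.399 with an estimated correlation).

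Lists not called held single genes that moved in either direction, and counts below are over all genes tested and then adjusted over the list alone. Of 25 TGF-β and BMP targets 4 rose and 5 fell (5 and 6). TGFBI and TGFB2 rose by 1.42 and 1.31. Of 20 genes of the endothelial to mesenchymal transition 7 rose and 6 fell (7 and 7), with the cadherin CDH2 at 1.15, the integrin ITGAV at 1.02 and the proteoglycan VCAN at −1.06. Of 31 vasomotor and gap junction genes 6 rose and 6 fell (7 and 9), including the prostaglandin synthase PTGS2 at 1.53, the potassium channel KCNJ2 at 1.01, GJA4 and GJA5. Of 22 hemostasis genes 5 rose and 3 fell (7 and 4), with TFPI2 at 1.51 and the plasminogen activator PLAT at −0.73. Of 30 fatty acid genes 2 rose and 3 fell (3 and 3), with the endothelial lipase LIPG at 1.44 and the fatty acid binding protein FABP4 at −1.59. Of 22 tip cell genes 7 rose and 3 fell (7 and 4), with ESM1 at 0.98. The interferon list had 4 higher and 1 lower of 29 (4 and 1). The venous list had 2 and 2 of 10 (2 and 2), with the adhesion molecule VCAM1 at 1.15. The lymphatic list had 2 and 2 of 7 (2 and 2), and the junction and barrier list had 3 and 3 of 32 (5 and 5). The unfolded protein response had 5 and 1 of 26 (8 and 2), hypoxia 5 and 2 of 22 (5 and 2), and the YAP and SRF targets 2 and 1 of 31 (2 and 1). The mitochondrially encoded genes had 3 and 0 of 13 (3 and 0). By edgeR, cholesterol synthesis had 0 and 0 of 24, with 2 lower at an unadjusted p below 0.05 and 1 lower by DESeq2. The leukocyte list had 0 and 0 of 3 by edgeR, by DESeq2 and at an unadjusted p below 0.05. The median, mean and test of a list differed in sign for 7 of the 28 lists in this comparison, none of them called: mural receptors, lymphatic, TGF-β and BMP, interferon, vasomotor, hypoxia, and junction and barrier.

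In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 918 genes higher and 764 lower with contact, 10.2% of those tested, and 162 and 113 of them changed over 2-fold. All 3 libraries of one group lay above all 3 of the other in 30.5% of the genes tested, where chance gives 10% on average. Genes of the same libraries move together, so chance can also give a share well above 10%. With upper-quartile factors the split was 769 higher and 1031 lower. The counts fell to 398 and 320 without monolayer replicate 1, 405 and 299 without monolayer replicate 3, 514 and 421 without contact replicate 2, and 486 and 325 without contact replicate 3, and the count higher grew to 1493 without monolayer replicate 2. Each gene said above to rise or fall with contact was called whichever library was left out.

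**Figure D1:**
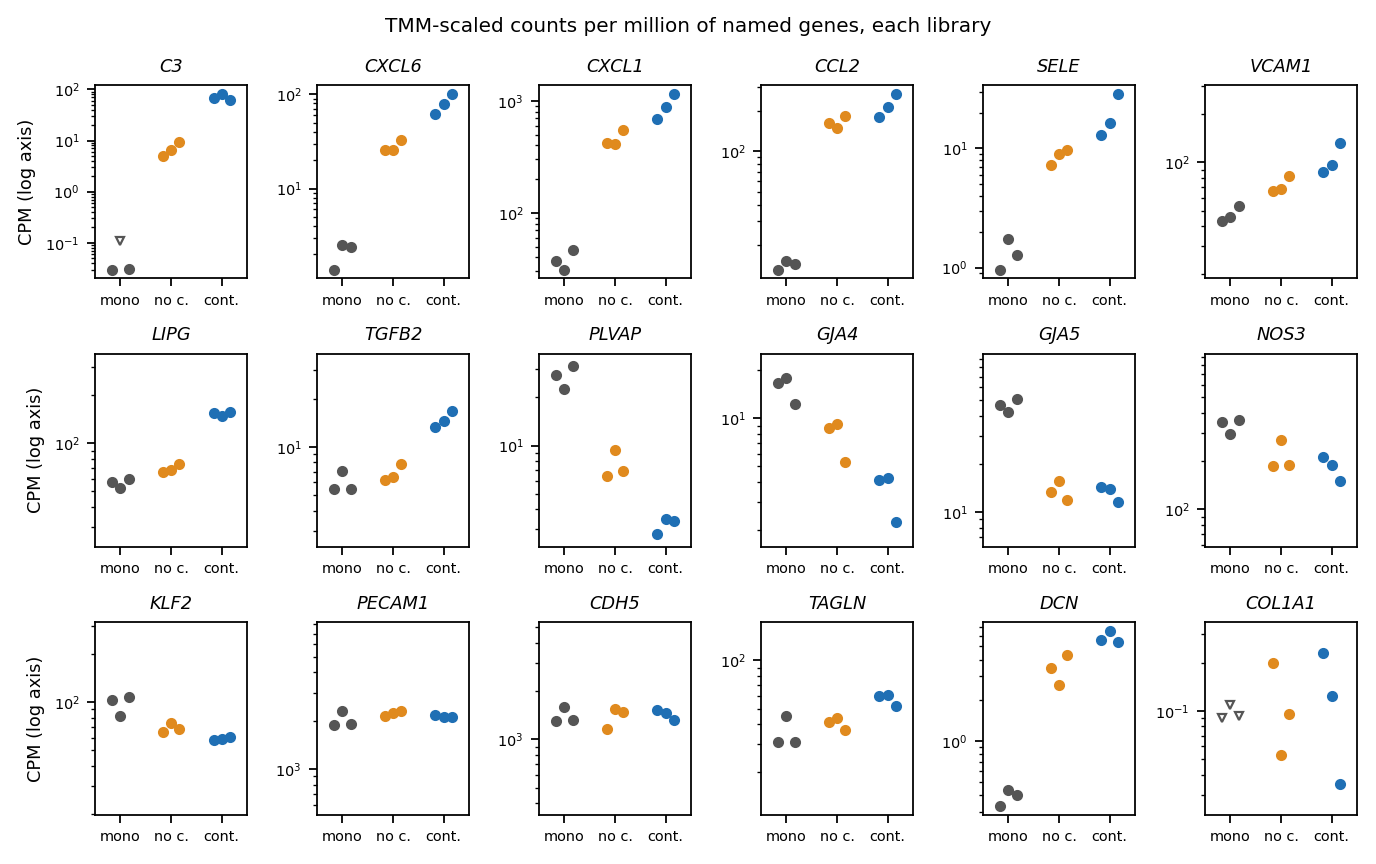
Levels of 18 genes in TMM-scaled CPM on a log axis, with 1 point per library and 3 libraries each for monolayer (grey), no contact (orange) and contact (blue); open triangles mark libraries with no count, drawn at the floor of 3 counts, which lies above points of 1 count. C3 rises from 0 or 1 counts per monolayer library to 69.8 CPM on average with contact and PLVAP falls from 27.2 to 3.23 CPM, while PECAM1 has group means of 2023 to 2229 CPM.

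No-contact against monolayer asks what the endothelial cells express differently when smooth muscle cells share only the medium. Among called genes with at least 10 CPM in the higher group and no overlap between the groups, chemokines led the rises. CXCL2 rose 15.5-fold, CXCL6 13.6-fold, CXCL1 12.1-fold and CCL2 11.6-fold, and the mitochondrial superoxide dismutase SOD2 (ENSG00000112096) rose 6.34-fold, from 62.4 ± 7.18 to 395 ± 46.9 CPM (SD, n = 3). The cytokine TNFSF15 rose 10.2-fold to 11.6 ± 2.53 CPM, CSF3 9.57-fold and CXCL8 7.71-fold, and the leukocyte adhesion receptor ICAM1 4.92-fold. C3, chosen here after its values were seen, had 549 counts against 2 in monolayer, a ratio of 343 (95% counting interval 94.6 to 2842). C1S, chosen in the same way, rose by 4.40 on the log2 scale to 5.07 ± 0.247 CPM. C3 and C1S both stayed below 10 CPM without contact, and here too a trace of smooth muscle RNA was not tested against monolayer. PLVAP, GJA5, SMAD6 and PITPNM3 fell by 1.85, 1.78, 1.75 and 1.63 on the log2 scale. TENT5A fell by 1.40, VCAN by 1.36, the matrix protein HMCN1 by 1.28 and MEST by 1.16. GJA5 stood at 13.6 ± 1.92 CPM, against 46.6 ± 4.45 in monolayer.

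Of the 32 inflammatory genes 22 rose without contact, none fell and 10 were not called (25 higher and 1 lower adjusted over the list alone), with a median of 1.51 (adjusted p = 4.25e-155, camera; adjusted p = 0.000453 with an estimated correlation). Of 22 tip cell genes 4 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.24; adjusted p = 0.000118). The sialomucin CD34 rose 2.29-fold and the chemokine receptor CXCR4 by 0.90 on the log2 scale, and IGFBP3 fell by 0.72. Of 26 matrix remodelling enzymes 5 rose and 2 fell (8 and 4 adjusted over the list alone; median 0.15; adjusted p = 0.0219), with CTSK at 1.38, ADAMTS9 at 0.89 and PLAT at −0.80. Apart from the inflammatory list, these calls were lost with an estimated correlation (adjusted p = 0.597 for both with an estimated correlation). The matrix remodelling call ended without monolayer replicate 1 (adjusted p = 0.0850), no-contact replicate 2 (0.126) or no-contact replicate 3 (0.0689).

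6 lists fell on balance without contact. Of 18 arterial genes 5 fell and 1 rose (7 and 2 adjusted over the list alone; median −0.17; adjusted p = 0.000546), with GJA5 and IGFBP3 lower and CXCR4 higher. Of 25 TGF-β and BMP targets 2 fell and 1 rose (7 and 3 adjusted over the list alone; median −0.19; adjusted p = 0.000118). The falls were SMAD6 and SMAD7, both inhibitors of the pathway that its activity induces, at −1.75 and −1.16. Of 18 Notch genes 2 fell and none rose (3 and 0 adjusted over the list alone; median −0.11; adjusted p = 0.0137), JAG2 at −0.73 among them. Of 16 KLF2 and KLF4 targets 4 fell and 2 rose (6 and 2 adjusted over the list alone; median −0.18; adjusted p = 0.0217). Of 31 vasomotor and gap junction genes 3 fell and 1 rose (6 and 4 adjusted over the list alone; median −0.09; adjusted p = 0.0219). Of 24 cholesterol synthesis genes edgeR called none, also when adjusted over the list alone, and DESeq2 called none, while 5 were lower at an unadjusted p below 0.05 (median −0.13; adjusted p = 0.0137). These calls were lost with an estimated correlation (adjusted p = 0.25 for the arterial list, 0.333 for TGF-β and BMP and 0.597 for the other 4 with an estimated correlation). The Notch call ended without no-contact replicate 1 (adjusted p = 0.0811), and the KLF2 and KLF4 call without that library (0.202) or no-contact replicate 3 (0.0507). The vasomotor call ended without no-contact replicate 1 (0.262) or monolayer replicate 2 (0.220) and with the stricter filter, and the cholesterol call without monolayer replicate 2 (0.679) or no-contact replicate 3 (0.0507). NOS3 and KLF2 fell by 0.65 and 0.50. NOS3 missed the threshold without monolayer replicates 1 (0.0672) or 3 (0.113) or no-contact replicates 1 (0.124) or 3 (0.0976), and KLF2 without monolayer replicates 1 (0.0648) or 3 (0.107) or no-contact replicate 1 (0.0770).

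Of the 41 cell cycle genes edgeR called none without contact, also when adjusted over the list alone, and the median was −0.10. At an unadjusted p below 0.05 there were 5, all lower, and DESeq2 called 1 lower, E2F1, as do the authors' tables. Of the 30 endothelial identity genes 2 rose and 3 fell (4 and 6 adjusted over the list alone). Neither list was called, although the cell cycle list passed the threshold in the opposite direction without monolayer replicate 2 (median 0.11).

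The same test called 255 genes higher and 146 lower, 2.44% of those tested, and 89 and 32 of them changed over 2-fold. The groups did not overlap in 15.3% of the genes tested, where chance gives 10% on average, with the same limit. The counts were 153 and 76 without monolayer replicate 3, 97 lower without monolayer replicate 1 and 78 lower without no-contact replicate 1. Of the named genes called in this comparison, 31 of 58 were called whichever library was left out. The median, mean and test of a list differed in sign for 5 lists, none of them called: mural matrix, mural receptors, leukocyte, interferon, and junction and barrier.

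Both co-cultures were compared with the same monolayer libraries. 214 genes were called higher in both and 112 lower in both, where 14.2 and 6.79 would fall together if the calls were independent and 20 simulations without any effect gave 0 and 0.05 on average. Over the 12169 genes with at least 2 CPM on average, the log2 fold changes had a correlation across genes of 0.711, against 0.494 in the simulations, and a covariance of 0.0793, against 0.0128. The share of genes with the same sign in both was 64.0%, below the 66.5% of the simulations. Genes are not independent replicates, and 3 controls cannot be split into 2 groups of at least 2, so part of the excess may come from the shared controls. The shared rises include C3, C1S, CXCL6, CXCL1, CXCL2 and CCL2, and the shared falls include PLVAP, GJA5, SMAD6, PITPNM3, VCAN and BGN, a matrix proteoglycan that fell by 1.14 with contact and 0.67 without. The counts were 128 and 57 without monolayer replicate 3, and the count lower was 67 without monolayer replicate 1 and 69 without no-contact replicate 1.

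**Figure D2:**
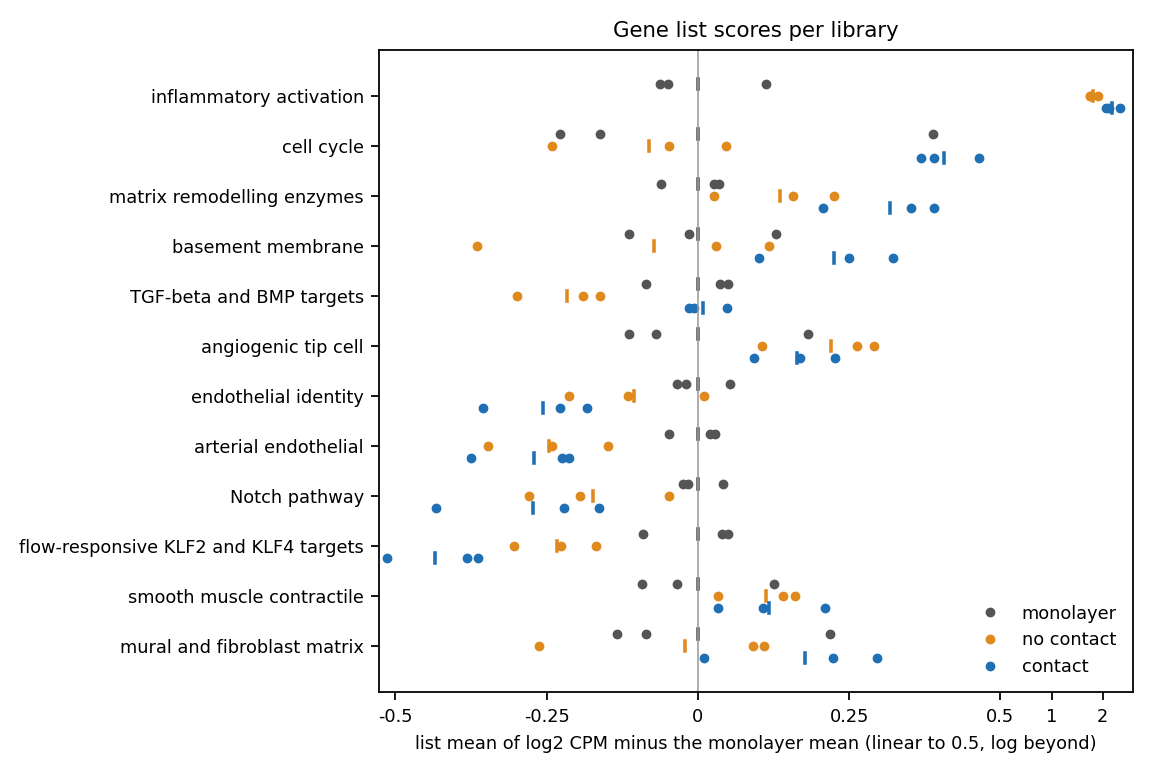
Scores of 12 gene lists, as the mean log2 CPM of a list's tested genes minus the monolayer mean, on an axis that is linear to 0.5 and logarithmic beyond; points are libraries, 3 each for monolayer (grey), no contact (orange) and contact (blue), and bars are group means. The inflammatory scores lie between 1.67 and 1.86 without contact and between 2.08 and 2.53 with it, and the cell cycle score of monolayer replicate 2, 0.39, lies among those of the contact libraries.

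Contact against no-contact asks what the position of the smooth muscle cells adds, and is also the direct test of whether the effects of the co-cultures differ. C3 and CXCL6 were among the genes that were higher again with contact. C3 rose by 3.29 ± 0.18 on the log2 scale (SE), from 7.05 ± 2.20 to 69.8 ± 9.76 CPM (SD, n = 3), and CXCL6 rose 2.83-fold. The complement proteases C1R and C1S rose by 1.37 and 1.27, where a trace of smooth muscle RNA among the reads was not excluded. The extracellular matrix protein PAPLN (ENSG00000100767, chromosome 14, 73237497 to 73274640) rose 2.64-fold to 15.6 ± 0.971 CPM. LIPG, the endothelial lipase (ENSG00000101670, chromosome 18, 49560699 to 49599185), rose 2.19-fold, from 69.5 ± 4.52 to 153 ± 4.83 CPM. In no-contact against monolayer it had a log2 fold change of 0.30, which edgeR did not call over all genes and DESeq2 called higher. SOX18 fell by 0.99 to 127 ± 32.5 CPM, PLVAP fell further by 1.22, and CXCR4 fell by 0.69. GJA5 differed by −0.03 and was not called, with 13.6 ± 1.92 CPM without contact and 13.3 ± 1.43 with it.

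Growth factor, matrix and inflammatory lists were higher with contact than without. Of 25 TGF-β and BMP targets 2 rose, TGFB2 by 1.12 and TGFBI to 162 ± 7.75 CPM from 80.7 ± 8.02, and none fell (8 and 0 adjusted over the list alone; median 0.16; adjusted p = 0.000278). Of 32 inflammatory genes 7 rose and none fell (14 and 1 adjusted over the list alone; median 0.51; adjusted p = 4.99e-08), with CXCL6, CSF3 at 1.65, IL6 at 1.02 and CXCL1 at 0.97. Of 41 cell cycle genes 12 rose and none fell (31 and 0 adjusted over the list alone; median 0.45; adjusted p = 1.78e-20), among them the kinesin KIF11 at 0.78 and the ribonucleotide reductase subunits RRM1 and RRM2 at 0.57 and 0.54. Of 21 basement membrane genes 1 rose, COL8A1 by 0.76 (3 and 0 adjusted over the list alone; median 0.26; adjusted p = 2.83e-05). Of 13 mitochondrially encoded genes 3 rose and none fell (3 and 0 adjusted over the list alone; median 0.26; adjusted p = 0.000125), with MT-ND4 at 0.53. Of 26 matrix remodelling enzymes 2 rose, ADAMTS1 by 0.71 and SERPINE2 by 0.63, and none fell (5 and 1 adjusted over the list alone; median 0.13; adjusted p = 0.0196). Of 20 genes of the endothelial to mesenchymal transition 3 rose and none fell (5 and 0 adjusted over the list alone; median 0.10; adjusted p = 0.0148), TGFB2, CDH2 at 0.64 and ITGAV at 0.70. Of 31 YAP and SRF targets 5 rose and 1 fell (11 and 4 adjusted over the list alone; median 0.12; adjusted p = 0.0133), with TGFB2 again among the rises. Of 24 cholesterol synthesis genes edgeR called none over all genes, with 6 higher at an unadjusted p below 0.05 and 2 higher by DESeq2, and 2 rose adjusted over the list alone (median 0.14; adjusted p = 0.0365). These calls were lost with an estimated correlation (adjusted p = 0.603 for most, 0.621 for matrix remodelling and 0.722 for cholesterol with an estimated correlation).

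The endothelial identity list was lower with contact than without, with 2 of 30 lower, SOX18 and PLVAP, and none higher (4 and 1 adjusted over the list alone; median −0.10; adjusted p = 0.00746). So was the KLF2 and KLF4 list, with 3 of 16 lower and ADAMTS1 higher (5 and 2 adjusted over the list alone; median −0.18; adjusted p = 0.0223), the falls being PLVAP, TXNIP at −0.60 and HMOX1 at −0.51. Both calls were lost with an estimated correlation (adjusted p = 0.621 and 0.603 with an estimated correlation). The identity call ended without no-contact replicate 2 (adjusted p = 0.0831), and the KLF2 and KLF4 call without no-contact replicates 2 (0.0810) or 3 (0.0644) or contact replicate 2 (0.110). Of the 18 Notch genes the ligand JAG1 and NOTCH2 rose, by 0.51 and 0.80, and the arterial ligand DLL4 fell by 0.72 (3 higher and 5 lower adjusted over the list alone), and the list was not called. Of 22 tip cell genes 1 rose and 5 fell (4 and 7 adjusted over the list alone), with the growth factor PGF at −0.90, CD34 at −0.63 and ESM1 at 0.55, and the list was not called. GJA4 fell by 1.12 and the lymphatic receptor LYVE1 by 0.97. The median, mean and test differed in sign for 4 lists, none of them called: arterial, tip cell, fatty acid handling and the unfolded protein response. Among all lists and comparisons, the calls that held with an estimated correlation were the inflammatory list in each co-culture against monolayer.

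The test called 273 genes higher and 138 lower, together 411 of the 16433 tested, with 29 and 12 over 2-fold. The groups did not overlap in 26.1% of the genes tested, where chance gives 10% on average but can give more, since genes move together. With upper-quartile factors the split was 217 and 201. Leaving out any library but contact replicate 1 moved the counts over 1.5 times. They were 21 and 6 without no-contact replicate 1, 27 and 8 without no-contact replicate 2, 739 and 528 without no-contact replicate 3, 33 and 8 without contact replicate 2, and 27 and 8 without contact replicate 3. Of the 58 genes that the naming rule took and the test called here, 12 were called whichever library was left out: C3, CXCL6, PAPLN, C1R, C1S, SOX18, PLVAP, CXCR4, TGFBI, TGFB2, ADAMTS1 and LIPG. The other 46 missed the threshold in at least 1 such fit, with an adjusted p of at most 0.206. The left-out library was no-contact replicate 1 for 45 of them (up to 0.197), no-contact replicate 2 for 41 (up to 0.203), contact replicate 2 for 42 (up to 0.164), contact replicate 3 for 40 (up to 0.206) and contact replicate 1 for 7 (up to 0.0716). Without no-contact replicate 1 the calls of the matrix remodelling list (adjusted p = 0.283), the transition list and the YAP and SRF list (both 0.0520) also ended, and the matrix remodelling call ended without contact replicate 1 (0.140). The cholesterol call ended without no-contact replicates 1 (0.0520) or 3 (0.216) or contact replicates 1 (0.210) or 2 (0.110), with the stricter filter and after thinning, and held in 7 of 15 alternatives in all.

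**Figure D3:**
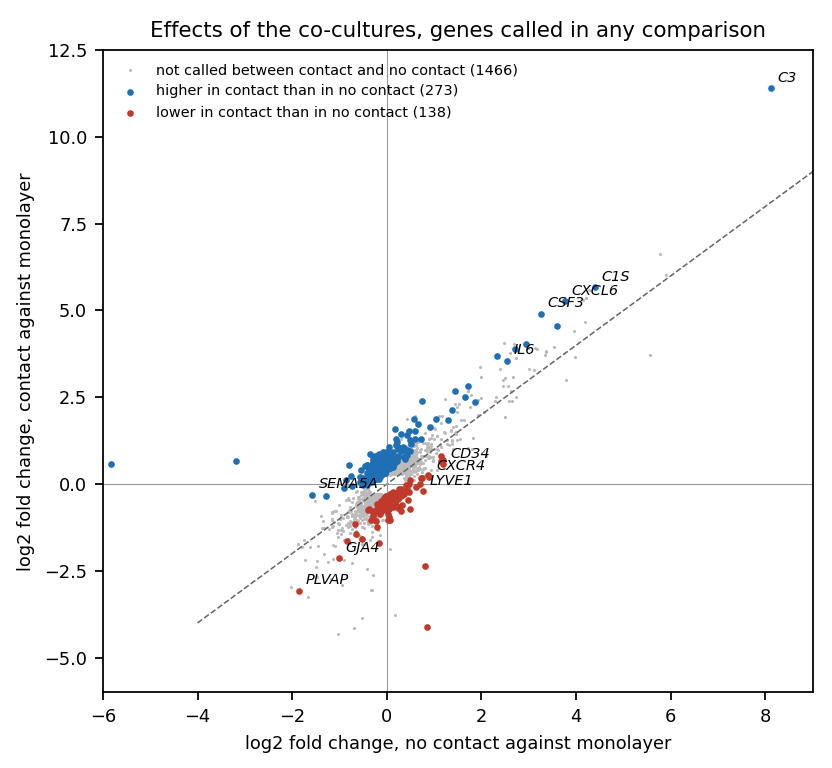
Log2 fold change of contact against monolayer (vertical axis) over that of no contact against monolayer (horizontal axis) for the genes called in any comparison, with 1 point per gene and a dashed line where both are equal. The 273 genes higher with contact than without (blue) lie above the line and the 138 lower (red) below it, with C3 at 8.11 and 11.40, where the monolayer held 2 counts in all and the fitted values are no measure of the fold.

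Transcripts of mural cells were followed as markers of the other cell type in the culture. Of 14 smooth muscle contractile genes 1 was higher with contact than in monolayer, TAGLN, at 57.6 ± 4.99 CPM (SD, n = 3) against 35.6 ± 8.02, and edgeR called none without contact or between the co-cultures (1 and 0, 0 and 0, and 4 and 1 adjusted over the list alone). Without contact 1 had an unadjusted p below 0.05 and DESeq2 called none. Between the co-cultures 4 higher and 1 lower had an unadjusted p below 0.05, and DESeq2 called TAGLN, TPM1 and MYL9 higher and HSPB6 lower, as do the authors' tables. ACTA2 stood at 8.51 ± 2.12, 9.30 ± 1.52 and 8.82 ± 0.414 CPM in monolayer, no-contact and contact. Of 22 matrix genes abundant in cultured smooth muscle 7 rose and 7 fell with contact (7 and 8 adjusted over the list alone) and 2 rose and 4 fell without (5 and 10 adjusted over the list alone). The proteoglycan DCN was at 0.389 ± 0.0535, 3.47 ± 0.885 and 5.84 ± 0.626 CPM. COL1A1, among the most abundant transcripts of cultured smooth muscle cells, had 0 counts in the monolayer libraries, 9 in the no-contact libraries and 12 in the contact libraries. Between contact and no-contact 2 of the matrix genes rose, COL8A1 and FBLN5 by 0.76 and 0.54, and BGN fell by 0.47 (3 and 1 adjusted over the list alone; median 0.24; adjusted p = 0.0160, camera). That call was lost with an estimated correlation (adjusted p = 0.621 with an estimated correlation) and without no-contact replicate 1 (0.283), contact replicate 1 (0.0506) or contact replicate 2 (0.103). COL8A1 missed the threshold without contact replicate 2 (0.0532), and FBLN5 and BGN without no-contact replicates 1 (0.197 and 0.116) or 2 (0.122 and 0.203) or contact replicates 2 (0.122 and 0.125) or 3 (0.203 and 0.206). FBLN5 stood at 53.2 ± 10.9, 36.9 ± 4.61 and 53.6 ± 5.98 CPM in monolayer, no-contact and contact. Its level with contact was thus near that of monolayer, and the lower level was that without contact. Of 8 mural receptors and regulators 1 rose and 1 fell with contact (3 and 2 adjusted over the list alone) and 1 fell in each of the other comparisons (1 and 1 in both adjusted over the list alone), that fall being RGS5, at −0.72 with contact and −0.37 without, both against monolayer. The RGS5 call without contact was lost without monolayer replicates 1 (0.0611) or 3 (0.121) or no-contact replicates 1 (0.0570) or 2 (0.0844).

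The authors' deposited tables call 1223 genes higher and 1071 lower with contact than in monolayer, 364 and 265 without contact, and 778 and 571 between contact and no-contact. Of the calls made here 1639 of 1682, 395 of 401 and 399 of 411 are among theirs, each in the same direction.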

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

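6 tests here were chosen after the result they concern was seen: the simulation of equal effects with its count of genes called whichever library was left out, the same count for CXCR4, the pooling of the 3 mural lists with its counts by other tools, the rises of mural matrix genes with a low monolayer level, the sides of monolayer under other settings, and the comparison of the median of the endothelial identity list with its called members. Thinning, used below, was likewise chosen after the data were seen. Groups of 3 libraries are too small for a test of single libraries far from the others, and no deposited data lie outside the comparisons.

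The effects of the co-cultures against monolayer differed for 411 genes, called between contact and no-contact. For each pair of groups the 6 libraries can be split in 10 ways, too few for a share under 0.05. As many calls as in the real split came in 1 of 10 splits, the real one, with 1682 genes in contact against monolayer, 401 in no-contact against monolayer and 411 in contact against no-contact, and the highest other split gave 0 in each case. Among the 3 groups 1533 genes differed, and of 100 splits of the 9 libraries 1 gave as many, the real one, with 343 in the highest other. A random assignment of these libraries to groups is thus argued against, at a share under 0.05. A chance difference between cultures is not excluded, since the labels do not say that the replicates of a group are separate cultures.

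For 7 lists the test between contact and no-contact passed while their medians against monolayer lay on opposite sides of 0. The medians between contact and no-contact were 0.24 for mural and fibroblast matrix, 0.16 for TGF-β and BMP targets, 0.10 for the endothelial to mesenchymal transition, 0.45 for the cell cycle, 0.26 for basement membrane, 0.12 for YAP and SRF targets and 0.26 for the mitochondrially encoded genes. The sides were not firm: 4 of the 7 lay on opposite sides without monolayer replicate 1 or 2, and 5 without contact replicate 1 or 3, with upper-quartile factors or after thinning; without monolayer replicate 2 the cell cycle list was higher without contact too (median 0.11, adjusted p = 0.0151), without monolayer replicate 3 the TGF-β and BMP list and without no-contact replicate 1 the mitochondrially encoded list lay on the same side in both. Lower sequencing depth of the no-contact libraries is argued against as the cause of the calls between the co-cultures, since 7 of the 7 lists, none of which held with an estimated correlation between genes, were called in the same direction after all libraries were thinned to the smallest total. One no-contact library standing apart stays open: without no-contact replicate 1, 4 of the 7 remained, and mural matrix, the transition list and YAP and SRF targets were lost, while mural matrix was also lost without contact replicate 1 or 2.

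Between contact and no-contact a few mural genes were called higher and a few endothelial identity genes lower, and a mixture of cell types was weighed for both. Of 44 mural genes 4.55% were called higher (2, COL8A1 and FBLN5, 95% interval 0.555 to 15.5) and 2 lower, BGN and RGS5, while 8 were higher and 3 lower adjusted over each list alone, and 7 and 3 by DESeq2. This share cannot weigh against carry-over of smooth muscle RNA. Some of these genes were already high in monolayer, such as SPARC at 2837 CPM and MCAM at 1977, where a little added RNA would not be called. The interval also treats genes as independent. Although the share for the mural matrix list (2 of 22, 1.12% to 29.2%) left the bound set beforehand inside its interval, carry-over of smooth muscle RNA into the contact libraries is argued against as the main source of the rises of COL8A1, FBLN5, C3, C1R and C1S, whose lower 95% limits were 4.56 CPM or more: for 18 mural matrix genes below 5 CPM in monolayer the upper 95% limits of the rise had a median of 0.213 CPM and a highest of 4.11 (DCN), and COL1A1 went from 0.116 to 0.129 CPM and COL3A1 from 2.16 to 2.03. The median says little alone, since THY1 and OGN had no count in any library. No smooth muscle library shows which of the 18 genes those cells express. A trace of such RNA stays open, since COL1A1 had counts in both co-cultures only (9 and 12) and DCN rose from 3.47 CPM without contact to 5.84 with it. A lower endothelial share of the RNA is argued against as the cause of the falls of SOX18 and PLVAP, by 0.99 and 1.22, since the endothelial identity list had a median of −0.10 with a lower quartile of −0.25, and PECAM1 and CDH5 had log2 fold changes of −0.06 and 0.04 and were not called, while a small shift in share stays open. The rule set beforehand against this cause was not met. It asked for a median of 0 or above, or as many members higher as lower, and 2 of 30 were lower and 0 higher.

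Of the genes called higher without contact, 25 were called higher again between no-contact and contact, and 23 genes called without contact moved back, 10 from lower to higher and 13 from higher to lower. Equal effects of both co-cultures were weighed with 5 genes, C3, CXCL6, C1R and C1S among them, called in both steps whichever library was left out. Simulations with equal effects gave at most 1 gene called further. They were redesigned after a first version called too many genes, and still called 383 genes higher without contact on average against 255 in the data. Chance moves through the shared no-contact libraries stay open for the 23 genes, although simulations gave at most 1. The simulated libraries hold no shift common to many genes of a library, so the bound set beforehand was too low. The bound for equal effects shares this limit, and the 5 genes were singled out because they survived the fits with 1 library left out. Equal effects are therefore argued against only for C3, which rose from 7.05 ± 2.20 to 69.8 ± 9.76 CPM between the co-cultures. For the others of the 5 they stay open. Without no-contact replicate 1 or contact replicate 2 only CXCR4 kept both calls. CXCR4 was the 1 gene called higher and then lower whichever library was left out, where the simulations gave 0 in that order. That bound is too low for the same reason, and CXCR4 was singled out because it survived those fits. Chance moves therefore stay open for CXCR4 too. For C3, CXCL6, C1R and C1S a graded response to the distance of the smooth muscle cells is a possible explanation, as is a difference in the dose of what they secrete, and neither was tested.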

How the results depend on the processing

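Thinning was chosen after the data were seen, and all other alternatives before. Unless a cause is given, the cause was not tested. Thinned to 19193002 counts per library, every count of called genes stayed within 1.5 times. With DESeq2 size factors 84 of 84 list results kept direction and side of the threshold, and 363 named gene results did, with 1 newly called. The DESeq2 test kept 316 named gene results, newly called 47 and lost 1. With estimated correlation 28 list calls were lost and 56 list results kept, and with fry, which also tests against no change rather than against the other genes, 26 and 58.

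A minimum fold of 1.2 asks for more by construction and gave 310 higher and 199 lower in contact against monolayer, 128 and 57 in no-contact against monolayer and 19 and 6 in contact against no-contact. The DESeq2 test gave 263 lower in no-contact against monolayer, 778 and 578 in contact against no-contact, 2501 among the 3 groups and 177 lower in both co-cultures. No filter gave 279 lower in no-contact against monolayer, 893 and 532 in contact against no-contact and 2592 among the groups. With the replicate number as a block, contact against no-contact gave 538 and 377, and the other counts stayed within 1.5 times, while the glycolysis call in contact against monolayer ended (adjusted p = 0.0514). Libraries sharing a number were no more alike than others (mean correlation of residuals 0.0022, range −0.083 to 0.108, against −0.0011), a hint from the data only.

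With 1 library left out, contact against monolayer ranged from 398 (without monolayer replicate 1) to 1493 (monolayer 2) higher and from 299 (monolayer 3) to 1133 (monolayer 2) lower. No-contact against monolayer ranged from 153 (monolayer 3) to 298 (monolayer 2) higher and from 76 (monolayer 3) to 177 (monolayer 2) lower. Contact against no-contact ranged from 21 (no-contact 1) to 739 (no-contact 3) higher and from 6 (no-contact 1) to 528 (no-contact 3) lower. The count among the groups ranged from 710 (monolayer 3) to 2361 (monolayer 2), that higher in both co-cultures from 128 (monolayer 3) to 256 (monolayer 2) and that lower in both from 57 (monolayer 3) to 142 (monolayer 2). Fewer libraries lower the power by construction, which does not account for the rises. In no-contact against monolayer 2 lists that were not called, with lower as the direction of the test, were called higher without monolayer replicate 2: the cell cycle list, whose median went from −0.10 to 0.11 (others down to −0.23), and the interferon list, from 0.03 to 0.28 (others down to −0.15).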

Other observations

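The complement genes were gathered as a group only after C3, C1S and C1R were seen among the largest changes, so their counts are descriptive. Of 30 genes listed, 17 were tested. With contact against monolayer 4 were higher and 2 lower, without contact 5 and 0, and between contact and no-contact 4 and 1. The rises in all 3 comparisons were C3, C1S, C1R and CD55, a membrane inhibitor of complement activation. C1R had log2 fold changes of 3.70 with contact and 2.33 without, both against monolayer, and CD55 of 0.72 and 0.39. CLU fell by 0.63 with contact against monolayer and by 0.44 between no-contact and contact.

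Of the 273 genes higher with contact than without, 171 were also called higher with contact than in monolayer, and 92 were called in neither comparison with monolayer. Of the 138 lower, 97 were also called lower with contact than in monolayer and 28 were called in neither.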
